A study of Homo sapiens with 2 samples.

How the data were processed

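Small RNA was sequenced from 2 samples of HTR-8/SVneo, a human trophoblast line immortalized with the SV40 T antigen. Per the labels' protocols, cells were starved in plain medium for 4 h and then kept for 24 h either with hepatocyte growth factor (HGF) at 50 ng/ml or in plain medium alone. Total RNA was isolated with Trizol, and libraries were made with the TruSeq Small RNA kit. Per the series design text, an Illumina Genome Analyzer IIx was used, reads were trimmed of adapters and low-quality bases in CLC Genomics Workbench 6.5.1, and the trimmed reads were mapped to miRBase release 21. The mismatches allowed, the treatment of reads that match several miRNAs and the genome build are not given in the sources used here. The labels name no molecular identifiers, so intervals and limits given for counts cover counting error only.

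The deposited table of all miRNAs holds whole-number read counts per mature miRNA, not normalized, and RPM (reads per miRNA relative to the library total), both as the authors deposited them. Some cells have digit-grouping commas, which were removed. Its columns carry codes rather than the sample titles, and they were matched to the control and the HGF sample through the table's own name and header. The authors' RPM columns equal count divided by a library total, with a largest deviation of 0.00660 RPM in the control and 0.00523 RPM in the HGF library. These totals were 7157914 and 2661958 reads, and the listed miRNAs hold 7157022 and 2661682 of them, so 892 and 276 reads (0.0125% and 0.0104%) belong to entries that are not listed. Per the file headers, the table lists miRNAs common to both libraries. Of its 1051 entries, 1031 had counts above 0 in both libraries, 20 had 0 in both and 0 had counts in exactly 1 library, so miRNAs seen in 1 library alone are not analysed here. Per the file headers, the deposited tables also give a signed fold change of normalized values and a p-value for each miRNA. The test behind these p-values is not given in the sources used here, and they were used here only to describe the authors' deposited table.

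There was 1 library per group. No test between conditions was therefore run, no p-value was computed, and ratios compare these 2 libraries, not the conditions. Counts were scaled by the listed total of each library. The log2 ratio of HGF over control was taken with a pseudocount of 0.5 count in each library. An exact (Clopper-Pearson) conditional binomial 95% interval was computed for each ratio, and exact binomial 95% intervals for shares of reads. An entry counted as measured with at least 10 RPM in at least 1 library and at least 20 counts summed over both. The rule of size was a 2-fold difference. For an entry at 0, the limit was taken as 3 counts, or 0.419 RPM in the control and 1.13 RPM in the HGF library.

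The 26 miRNA lists (genomic clusters, seed families, miRNAs reported to target the HGF receptor MET, markers of other cell types, and miRBase entries said to overlap other RNA classes) were fixed before the data were examined, as were the settings, the main alternatives and the rule for named miRNAs. List members are either arm of a listed stem. For each list with at least 3 measured members, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 10 bins, as a description of these libraries. A 95% range of each median for counting error came from resampled counts. The rule named the 12 highest and 12 lowest log2 ratios among measured miRNAs with at least 50 RPM in 1 library, the 10 most abundant miRNAs, the highest, lowest and most abundant measured member of each list, and both arms of up to 3 precursors whose arms differ by more than 2 on the log2 scale. It gave 76 miRNAs, and no precursor met its last part, since the largest of 115 differences was 1.76.

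Positions and precursor sequences were taken by miRNA name from GENCODE release 29 (GRCh38), and the GC content of the precursor was found for 428 of the 429 measured miRNAs. A miRNA was said to have a near-copy when a more abundant entry shared a window of 20 bases in the counted arm's side of the precursor with at least 18 matches, or when their genes overlap on opposite strands. Such miRNAs are uncertain wherever reads may have been split or assigned between them, or counted in each.

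Alternatives were scaling by the trimmed mean of M-values (trimming 30% of ratios and 5% of abundances), by the median of ratios, or by the total without the 5 most abundant miRNAs; a pseudocount of 5; no filter on low counts; at least 100 RPM in 1 library; 1.5-fold and 4-fold rules; 5 expression bins; and shares without the most abundant miRNA. Keeping repeated entries of a mature miRNA apart changed nothing, since the table holds 0 repeated names. The ratio step was tested on simulated counts for the 429 measured miRNAs: the interval held the true value for 94.6% of them, and the sign was right for 98.0% of 99 miRNAs changed 2-fold and 100% of 101 changed 4-fold. The simulated counts varied by counting error alone, as the interval assumes. This checks the calculation only, since variation between cultures or libraries was not simulated. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with Matplotlib 3.10.9.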

Results

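miRNAs were profiled by small RNA sequencing in 2 samples of HTR-8/SVneo cells, 1 kept in plain medium (control) and 1 treated for 24 h with HGF, the ligand of the MET receptor tyrosine kinase. The comparison asks which miRNAs differ between HGF-treated and untreated trophoblast cells. The control library held 7157022 miRNA reads and the HGF library 2661682, a depth 2.69 times lower, so a level of 1 RPM (a count scaled to the library total) stood for 7.16 reads and 2.66 reads respectively. At least 10 counts were found for 709 of the 1051 listed miRNAs in the control and for 540 in the HGF library. There was 1 library per group, so no difference below has a replicate check, each ratio compares these 2 libraries and not the conditions, and intervals cover counting error only.

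Both libraries had nearly the same abundant miRNAs at nearly the same levels. miR-21-5p, from a gene overlapping an exon of VMP1 on chromosome 17 (59841266 to 59841337, GRCh38), was the most abundant by mean RPM, with 10.4% of control reads (exact 95% interval 10.3% to 10.4%) and 11.1% of HGF reads (11.1% to 11.2%). It was followed by miR-22-3p, miR-92a-3p, miR-191-5p, let-7a-5p, miR-30a-5p, miR-10a-5p, miR-16-5p, miR-26a-5p and let-7f-5p. Together these 10 miRNAs held 53.4% of reads in the control (53.4% to 53.4%) and 54.4% in the HGF library (54.3% to 54.4%). Their log2 ratios lay between -0.38 for let-7f-5p (interval -0.39 to -0.37) and 0.44 for miR-16-5p (0.43 to 0.45), with 0.11 for miR-21-5p and 0.0053 for miR-30a-5p, which was -0.038 with scaling by the trimmed mean of M-values and -0.012 with the total without the 5 most abundant miRNAs.

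Of the 429 measured miRNAs, 373 (86.9%) were within 2-fold between the libraries and 308 (71.8%) within 1.5-fold. The median log2 ratio was -0.034. In the HGF library 26 miRNAs were at least 2-fold higher and 30 at least 2-fold lower, and the whole counting interval lay beyond 2-fold for 19 and 17 of them. Counts redrawn 100 times from equal shares at these depths gave a median of 0 in each direction and at most 1 higher and 2 lower. Across miRNAs, which are not independent replicates, Pearson's r between the libraries was 0.937 for the log2 of RPM with 1 RPM added. With no filter on low counts, 159 entries were 2-fold higher and 89 lower, and with at least 100 RPM in 1 library these numbers were 8 and 9. Without the filter, an entry with 1 count in each library has a log2 ratio of 1.43 from the difference in depth alone. Entries seen in 1 library alone are also not listed, so the excess of higher entries without a filter does not show higher levels.

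The entries that were highest in the HGF library were mostly GC-rich miRBase entries near the limit of detection in the control. The 15 entries over 8-fold higher had a median precursor GC of 76.3%, against 51.1% for the measured miRNAs. miR-6087 went from 5 counts (0.699 RPM) to 1234 counts (464 RPM), a log2 ratio of 9.24, or 604-fold (284 to 2047), and 8.38 with a pseudocount of 5. miR-663a had 1 count in the control and 180 in the HGF library, a log2 ratio of 8.34 with a wide interval of 6.42 to 14.23, and 6.37 with a pseudocount of 5. miR-3960 went from 8 to 741 counts (7.87, 6.97 to 9.18) and miR-4792 from 180 to 6349 counts, or 25.2 to 2385 RPM (6.56, 6.35 to 6.79). Among entries with at least 50 RPM in 1 library, miR-3141 (6.01), miR-4634 (5.75), miR-7704 (5.26) and miR-4454 (3.24, from 598 to 2099 counts) followed. By position, MIR6087 lies on chromosome X (109054542 to 109054590) outside other annotated genes, MIR663A on chromosome 20 (26208186 to 26208278) in an exon of its host transcript, and MIR3960 on chromosome 9 (127785833 to 127785923) over an exon of CDK9.

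Several of these entries belong to a list, fixed beforehand, of miRBase entries said to overlap other RNA classes such as ribosomal, transfer and small nuclear RNA; miR-663a, miR-3141 and miR-4634 are not on it, and the overlap was not tested on sequences here. Of its 20 measured members, 13 were at least 2-fold higher in the HGF library and 0 at least 2-fold lower. Its median log2 ratio was 2.40 (counting range 2.13 to 2.62), above all 10000 random lists (95% of which lay between -0.35 and 0.22), but 1.43 with no filter and 5.26 with at least 100 RPM in 1 library. The unfiltered 1.43 is also the value of members with 1 count in each library, such as miR-4485-5p (interval -4.87 to 7.72), so it does not show a rise. The share of reads held by the list was 0.0857% in the control (0.0836% to 0.0879%) and 0.565% in the HGF library (0.556% to 0.575%). Besides the entries above, miR-1246, said to match U2 small nuclear RNA, had a log2 ratio of 1.40 (1.15 to 1.66). The lowest member was miR-3607-3p, said to lie in a small nucleolar RNA, at -0.46 (-0.93 to -0.035). Without this list, 13 miRNAs remained at least 2-fold higher.

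Higher miRNAs outside that list included several well-known ones. miR-33a-5p, from an intron of the sterol regulator SREBF2 (chromosome 22, 41900944 to 41901012), had 20.96 RPM in the control and 65.7 RPM in the HGF library, a log2 ratio of 1.65 (1.33 to 1.97). It has a near-copy, miR-33b-5p, from an intron of SREBF1, whose own log2 ratio was 0.77 (chosen after its values were seen). miR-222-5p was 2.32-fold higher (1.87 to 2.87) while the abundant arm miR-222-3p had a log2 ratio of -0.44 (-0.47 to -0.42). miR-193a-3p, a near-copy of miR-193b-3p, was 2.16-fold higher (1.74 to 2.67). The hypoxia-induced miR-210-3p, from 1728 to 1254 counts or 241 to 471 RPM, was 1.95-fold higher (1.81 to 2.10), just under the 2-fold rule. miR-205-5p, a miRNA of epithelial cells below 50 RPM in both libraries, went from 2 to 39 counts, or 0.279 to 14.7 RPM, a log2 ratio of 5.41 (3.76 to 8.81; 4.08 with a pseudocount of 5), and was the 1 measured member of the list of the miR-200 family and miR-205.

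**Figure D1:**
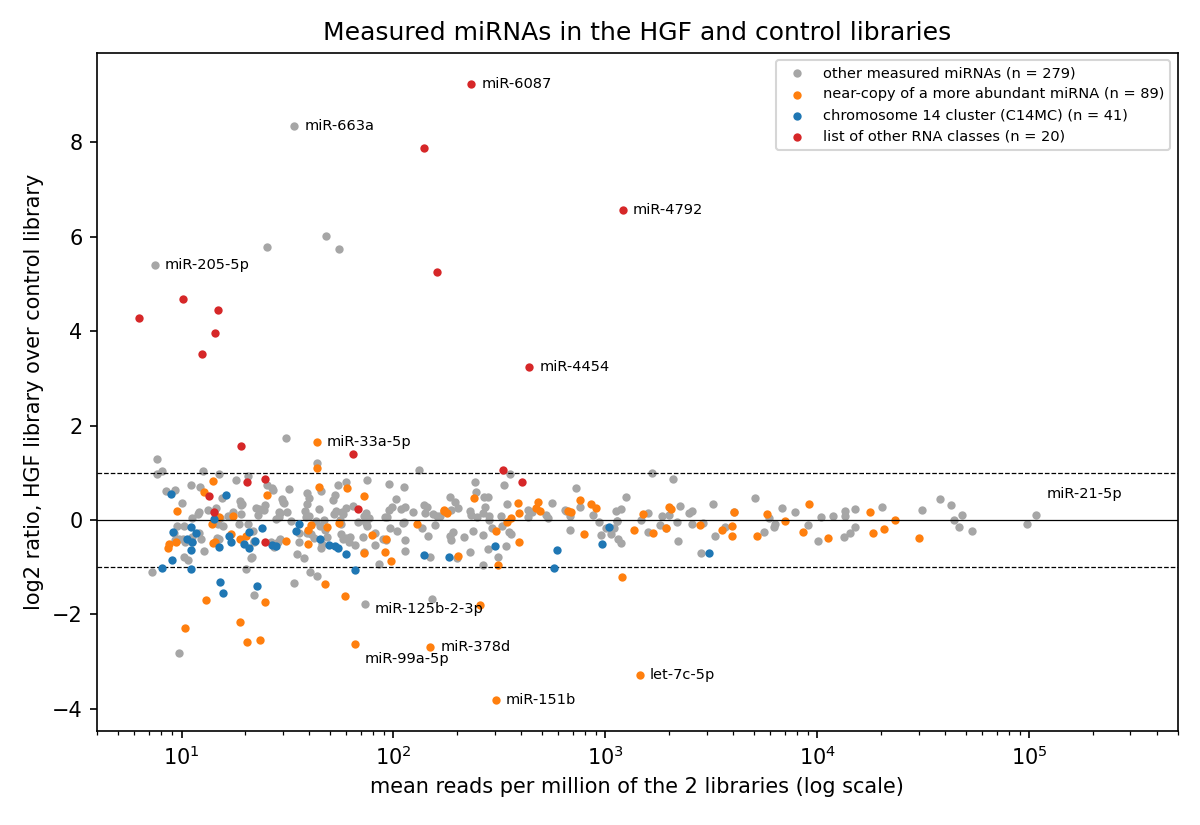
Log2 ratio of the HGF library over the control library (y axis) against the mean RPM of both libraries (x axis, log scale) for the 429 measured miRNAs, 1 point each. Dashed lines mark 2-fold. The 20 measured members of the list of other RNA classes (red), an overlap not tested here, reach 9.24, near-copies of more abundant miRNAs (orange) reach -3.81, and the 41 members of the chromosome 14 cluster (blue) lie mostly below 0.

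The miRNAs that were lowest in the HGF library were mostly minor members of families with a more abundant, near-identical member. miR-151b went from 4054 to 107 counts, a log2 ratio of -3.81 (-4.11 to -3.54), while its near-copy miR-151a-5p had 0.087. let-7c-5p went from 18825 to 716 counts, or 2630 to 269 RPM (-3.29, -3.40 to -3.18), while let-7a-5p had -0.15. miR-378d (-2.70) and miR-378c (-1.80) were lower while miR-378a-3p, the abundant member, had 0.032, and miR-320b (-1.61) was lower while miR-320a had -0.020. miR-99a-5p was 6.21-fold lower (4.69 to 8.58) while its near-copy miR-100-5p had a log2 ratio of -0.19. miR-146a-5p, which NF-kappaB induces, was 2.57-fold lower (2.01 to 3.36) and its near-copy miR-146b-5p had 0.046. The abundant members of these families were named after their values were seen. Of the 30 miRNAs at least 2-fold lower, 16 had a more abundant near-copy, and 14 remained without these.

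Among the lower miRNAs without such a near-copy, miR-125b-2-3p was 3.45-fold lower (2.78 to 4.38; 812 to 87 counts), miR-26a-2-3p 2.29-fold lower (1.79 to 3.01) and miR-92a-1-5p, the minor arm of a miR-17-92 cluster member, 2.16-fold lower (1.68 to 2.85). MIR125B2 (16590237 to 16590325), MIR99A (16539089 to 16539169) and MIRLET7C (16539828 to 16539911) all lie in introns of the long noncoding RNA gene MIR99AHG on chromosome 21 (15928296 to 16645065). Genes that overlap on opposite strands leave other lower miRNAs uncertain, and miR-7-5p and miR-3184-5p are counted among the 16 for this reason. The more abundant partner of miR-7-5p, miR-3529-3p, is counted among the 14 and is uncertain too. miR-3529-3p (-1.68, -1.90 to -1.46) and miR-7-5p (-2.16, -2.98 to -1.50) share a locus where genes overlap on opposite strands, as do miR-3184-5p (-1.20, -1.27 to -1.13) and miR-423-3p (0.082). Their reads cannot be told apart without knowing how strand was used. Counts were unequal in these pairs, with 18 for miR-7-5p and 192 for miR-3529-3p, and 1935 for miR-3184-5p and 32389 for miR-423-3p, in the HGF library. The other arms of the last pair of genes, miR-3184-3p and miR-423-5p, had nearly equal counts, 14624 and 14616 in the control and 4846 and 4855 in the HGF library. So did miR-103a-3p and miR-103b, with 27192 and 27214 in the control and 11324 and 11339 in the HGF library. Strand therefore did not separate the reads of these nearly equal pairs. Counts this close are unlikely under a random split of shared reads. Whether such reads were counted in each entry or divided evenly is not known. If they were counted in each, the read totals hold them more than once, and both entries of a pair rest on the same reads.

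Most members of the chromosome 14 miRNA cluster (C14MC), an imprinted cluster active in placenta, were lower in the HGF library. Of its 41 measured members, 38 had a log2 ratio below 0. For 25 the counting interval lay below 0, for 0 above it, and 7 were at least 2-fold lower. The median log2 ratio was -0.53 (counting range -0.64 to -0.46), below all 10000 random lists (95% between -0.34 and 0.14), and the summed level went from 9348 RPM to 6181 RPM. Random lists drew miRNAs singly, while neighbours in a cluster may be cut from 1 transcript, so the random range may be too narrow for this cluster. The most abundant member, miR-127-3p, was 1.62-fold lower (1.57 to 1.66; 27192 to 6248 counts). miR-487a-3p was the lowest (-1.55, -2.31 to -0.92), with miR-487b-3p as a near-copy, and miR-433-3p the highest (0.55, -0.18 to 1.22). The 40 measured members with 1 locus span chromosome 14 from 100869060 to 101066801. For C19MC, the primate-specific placental cluster on chromosome 19, the list held 37 stems, but only 6 entries were among the deposited counts. These 6 had 0 counts in both libraries, which allows up to 0.419 RPM each in the control and 1.13 RPM in the HGF library. The other members were not listed, so their levels are not known here.

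**Figure D2:**
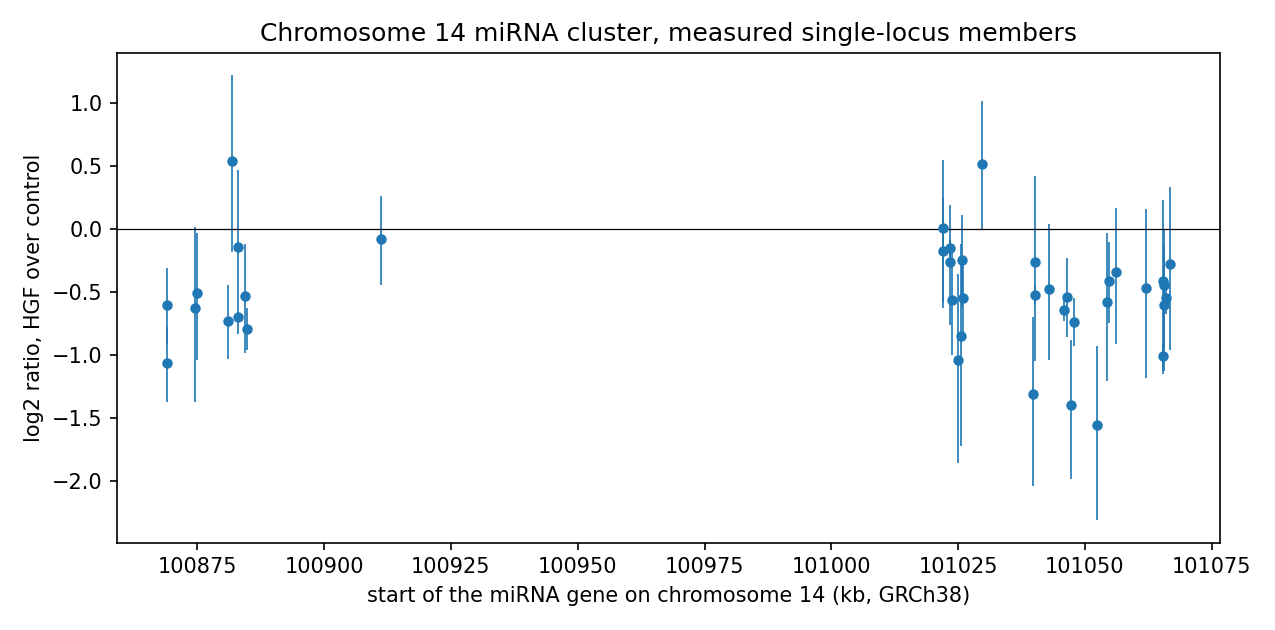
Log2 ratio of the HGF library over the control library (y axis) for the 40 measured C14MC members with 1 locus, against the start of each miRNA gene on chromosome 14 in kb (x axis, GRCh38). Bars are exact 95% intervals for counting error, and most points lie below 0 along the whole region, from -1.55 to 0.55.

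The miR-34 and miR-449 family and miRNAs reported to target MET had medians above 0, the second of them outside the central 95% of random lists. Among 5 measured members of that family, which p53 and multiciliated cell programmes induce, 5 had a log2 ratio above 0 and 1 was at least 2-fold higher. Their median was 0.60 (counting range 0.22 to 0.93), at percentile 96.6 of random lists, with miR-34c-5p at 1.74 (1.36 to 2.13; 102 to 127 counts), miR-34a-5p at 0.85 (0.61 to 1.08) and miR-449c-5p at 0.15 (-0.24 to 0.53). Of the 7 measured MET-targeting miRNAs, 6 lay above 0 and 2 were at least 2-fold higher, with a median of 0.60 (0.33 to 0.93) at percentile 98.8. This list shares miR-34a-5p, miR-34c-5p, miR-449a and miR-449b-5p with the family above, so the 2 medians are not independent observations. With 16 lists placed, a median outside the central 95% can also arise among random lists. The most abundant member of the MET-targeting list, miR-101-3p, had 0.34 (0.31 to 0.38) and its lowest, miR-23b-3p, -0.050 (-0.16 to 0.060). With at least 100 RPM in 1 library, a level that miR-34a-5p and miR-34c-5p did not reach, the median of this list was 0.15.

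The other growth- and differentiation-related families had medians inside the range of random lists. In the let-7 family, which represses growth genes, 11 of 18 measured members lay below 0 and the median was -0.14 (percentile 20.7), with let-7i-3p highest at 0.74. The miR-17-92 cluster and its paralogs had 12 of 16 below 0, 2 at least 2-fold lower and a median of -0.17 (percentile 16.5), with miR-18b-5p, a near-copy of miR-18a-5p, lowest at -2.30 and miR-106b-3p highest at 0.22. In the group of miR-10, miR-99, miR-100 and miR-125 7 of 14 members lay on each side of 0, and miR-100-3p was highest at 0.81; the median of 0.032 (percentile 62.5) was -0.011 with scaling by the trimmed mean of M-values and -0.0074 with at least 100 RPM. The miR-15/16 family ranged from -0.96 for miR-424-3p to 0.80 for miR-497-5p (median 0.053, percentile 56.1), a median that was -0.16 with no filter and -0.24 with at least 100 RPM in 1 library. Inflammation and growth-factor responsive miRNAs had a median of -0.024 (percentile 49.8), with miR-146a-5p lowest and miR-210-3p highest, and the median was above 0 with a pseudocount of 5 (0.028), no filter (0.046) or at least 100 RPM (0.076).

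Smaller families gave like values. The median was 0.0053 for 11 members of the miR-30 family (percentile 48.4, -0.038 with scaling by the trimmed mean of M-values), 0.16 for 8 of the miR-181 family (percentile 78.1, lowest miR-181a-2-3p at -0.95), 0.21 for 5 of the miR-29 family (percentile 83.6), -0.044 for 9 of the miR-23/27/24 clusters (percentile 43.9), -0.10 for 4 of miR-221 and miR-222 (percentile 25.8) and 0.067 for 4 of the cluster of miR-183, miR-96 and miR-182 (percentile 73.3, -0.088 with no filter and -0.11 with at least 100 RPM). miR-143-3p, the 1 measured member of the cluster of miR-143 and miR-145, had -0.17. The miR-371-373 cluster and the imprinted miR-675 and miR-483 are not analysed here.

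Markers of other cell types were few and did not move together. For blood cells, miR-486-5p was 1.84-fold higher (1.78 to 1.89) and miR-486-3p 1.84-fold lower (1.57 to 2.17), though their genes overlap on opposite strands. For endothelium, miR-126-5p had a log2 ratio of 0.24 (0.18 to 0.30) and miR-126-3p 0.38 (0.24 to 0.52). For neurons the median of 3 members was 0.086 (percentile 52.6; -0.46 with no filter), with miR-137 at -0.46, miR-9-5p at 0.086 and miR-9-3p at 0.17. For pancreas and endocrine cells, 2 members were measured, miR-7-5p at -2.16 and miR-7-1-3p at -0.80, and for muscle and liver 0.

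**Figure D3:**
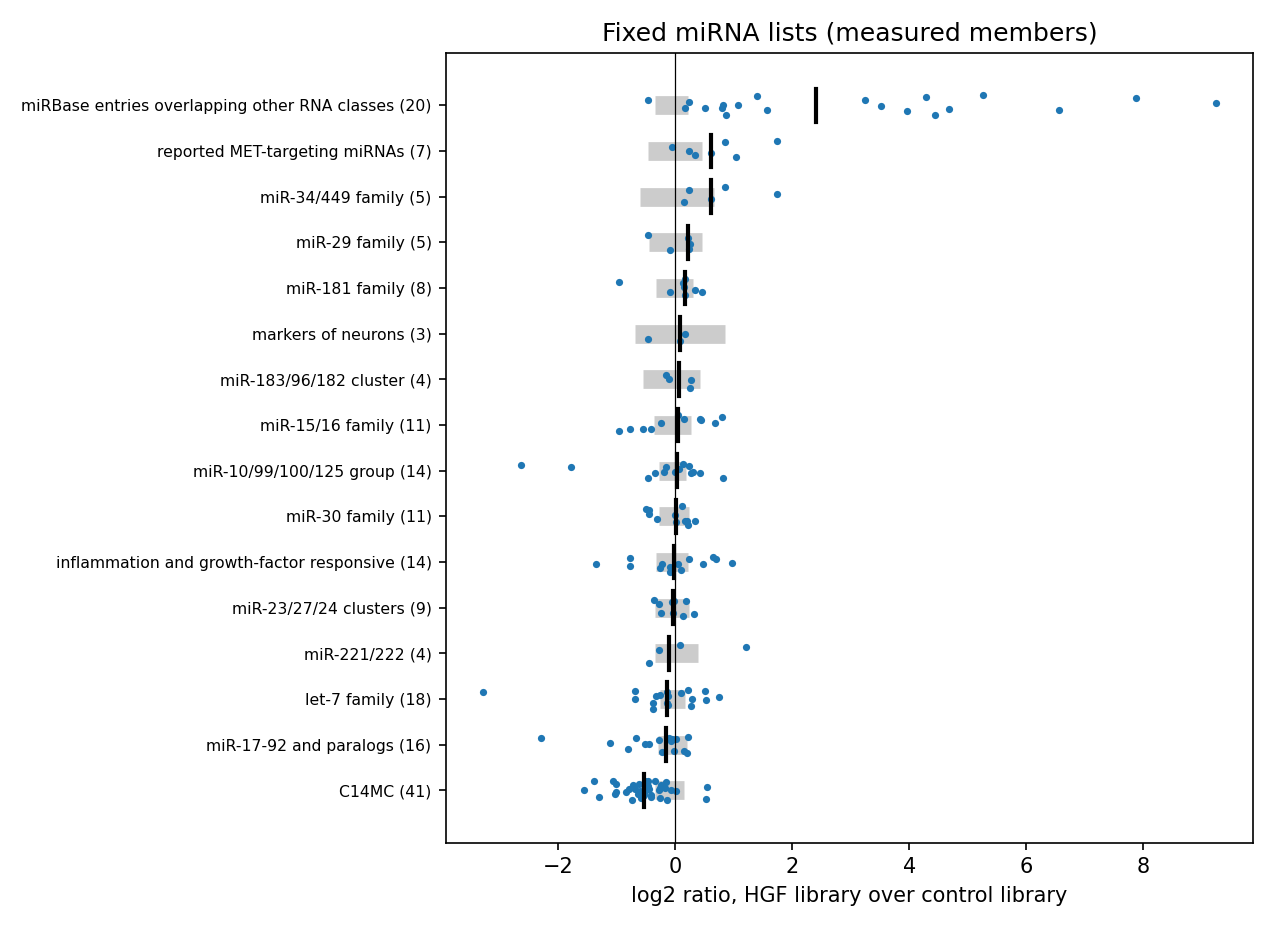
Log2 ratio of the HGF library over the control library (x axis) for the measured members of the 16 lists with at least 3 of them (points; numbers in brackets on the y axis), with the list median (black bar) and the central 95% of medians of 10000 matched random lists (grey). The medians of C14MC, of the MET-targeting list and of the list of other RNA classes lie outside the grey range.

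The authors' deposited table of differences lists 207 miRNAs, 97 higher and 110 lower in the HGF library. In the authors' deposited table the signed fold changes run from -16.36 to 663.64. Its header names a p of 0.05 and a fold change of 2, and 26 of the listed miRNAs are at least 2-fold higher and 28 at least 2-fold lower, while 153 have a smaller fold, down to 1.05. The 207 are those with a p-value of at most 0.05 in the authors' deposited table of all miRNAs. For all 207 the log2 ratio computed here had the same direction, and 50 of the 54 with a 2-fold change in the authors' deposited table were also measured and at least 2-fold here. Both rest on the same counts of the same 2 libraries, so the shared direction was largely set in advance and is no separate check. Of the 56 miRNAs past the 2-fold rule here, 6 are not among those 54.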

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

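Leaving out the list of other RNA classes or near-copies, and scaling without that list, were chosen after seeing the data. The number of higher miRNAs (26) moved to 159 without a filter, 8 with at least 100 RPM, 58 at 1.5-fold, 15 at 4-fold and 13 without the list of other RNA classes; it was 23 to 27 under the remaining alternatives. The number of lower miRNAs (30) moved to 89, 9, 63 and 9 under the same settings and to 14 without near-copies; otherwise it was 26 to 31. These rules admit fewer or more miRNAs by construction. Without a filter, entries with 1 count in each library also count as 2-fold higher, because of the lower depth of the HGF library. Of 111 list medians under alternatives, 95 stayed within their counting range. With at least 100 RPM the median was -0.67 for C14MC, 5.26 for other RNA classes, 0.15 for MET-targeting miRNAs, -0.067 for miR-17-92, -0.20 for let-7, -0.28 for miR-221 and miR-222, 0.14 for miR-30 and -0.24 for miR-15/16. Without a filter it was 1.43 for other RNA classes, 0.94 for MET-targeting miRNAs, -0.26 for miR-17-92 and -0.46 for neurons. The value of 1.43 is also that of an entry with 1 count in each library. A pseudocount of 5 gave -0.45 for C14MC. Scaling by the trimmed mean of M-values gave -0.087 for miR-23/27/24 and -0.038 for miR-30, and the total without the 5 most abundant gave -0.012 for miR-30. The cause of the list changes was not tested. The side of the central 95% was the same for 16 of 16 lists with 5 expression bins. The 10 most abundant miRNAs after removal of the first held 50.6% and 51.2%. Among 506 values of the 76 named miRNAs, 473 stayed within their counting interval and 33 did not: 1 was miR-663a with a pseudocount of 5 (6.37), the others came from scaling. Of the values, 2 changed sign, both of miR-30a-5p, and miR-424-3p passed 2-fold under the trimmed mean. The same direction as the authors' deposited table held for 207 of 207 there too, which rests on the same counts and is no separate check. No paired analysis was possible because there was 1 library per group. Depth limits the HGF library most, where 540 miRNAs had at least 10 counts.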

Other observations

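The tests in this part were chosen after the results were seen, except those of neighbouring genes and of scaling, where 1 of the scalings was added afterwards.

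miRNAs whose genes lie within 10000 bp of each other on a strand are often cut from 1 transcript, so they were compared as groups, leaving out near-copies and the list of other RNA classes. Over 22 such clusters with 72 miRNA genes, the pooled SD of log2 ratios within clusters was 0.36, against a median of 0.44 when ratios were shuffled among genes of like read count, and 0.230% of 10000 shuffles were as low. This rests on the chromosome 14 region: over the other 18 clusters with 45 genes the SD was 0.35 against 0.37, at percentile 29.2, so it is open whether neighbours in general moved together. By median, MIR493 to MIR136 on chromosome 14 (-0.66) and MIR2682 with MIR137 on chromosome 1 (-0.60) were the lowest groups, and MIR3677 with MIR940 on chromosome 16 (0.23) and MIR449A with MIR449C on chromosome 5 (0.20) the highest.

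Arms of the same miRNA sometimes differed in their ratios. Among 115 pairs of measured arms, the difference for miR-222 was 1.66 (1.21 for the 5p arm, -0.44 for the 3p arm) and for miR-32 1.40 (0.67 and -0.73), both from a single gene. The highest difference, 1.76, was in miR-486 (0.88 and -0.88), which has more than 1 gene, overlapping on opposite strands, so its reads are uncertain.

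The 26 miRNAs at least 2-fold higher in the HGF library were split evenly between 1 list and other miRNAs, 13 each. Counting error from the lower depth of the HGF library is argued against for 23 of the 26, whose counts exclude equal shares at these depths by exact intervals widened to a 5% error over the 429 measured miRNAs, and counts redrawn from equal shares gave at most 1 higher miRNA. Fragments of other abundant RNAs counted as miRNAs are a candidate explanation: the list fixed beforehand held 13 of the 26, where 1.21 would be its share, although a class of RNA was given to only 10 of its 20 measured members, 5 of them at least 2-fold higher, and not to miR-6087, miR-3960, miR-4792 or miR-7704, its highest, and overlap with other RNAs was not tested on sequences here. GC content stays open too: of 35 miRNAs off the list in the top 10% of precursor GC, 4 (11.4%, exact 95% interval 3.20% to 26.7%) were at least 2-fold higher, against 9 of 374 with lower GC, while their median log2 ratio was 0.29, and the GC of the sequenced parts was not measured. What raised these entries, whether HGF or a difference between cultures or libraries, also stays open, since treatment and library coincide.

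The 30 miRNAs at least 2-fold lower may in part reflect reads shared with near-identical, more abundant miRNAs. Near-copies made up 16 of the 30 where 7.11 would be their share, and their median log2 ratio of -0.21 over 97 members lay at percentile 0.160 of matched random lists; let-7c-5p went from 5.37% to 0.609% of the counts of let-7a-5p, miR-378d from 4.44% to 0.667% of miR-378a-3p, miR-151b from 4.32% to 0.289% of miR-151a-5p and miR-320c from 3.53% to 0.602% of miR-320a. Counting error from the lower depth is argued against for 27 of the 30 by the same widened intervals, and the redrawn counts gave at most 2 lower miRNAs. For the MIR99AHG locus, sharing is argued against for miR-125b-2-3p, which has no more abundant near-copy by this search and a log2 ratio of -1.79 (-2.13 to -1.47), and stays open for let-7c-5p and miR-99a-5p. How often sequencing errors were assigned to near-copies in each library was not tested, and an effect of HGF on these genes remains untested.

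The lower level of C14MC kept its direction in each technical test run. The choice among 5 scalings is argued against, as the median lay between -0.58 and -0.53 under them. Against scaling by the total, the others shifted all ratios alike, by -0.043 to 0.0069, so only that choice was tested. Shared reads are argued against, with a median of -0.55 for the 33 members that have no more abundant near-copy, 32 of them below 0. GC content is argued against as the whole cause. Subtracting a linear GC trend fitted to other miRNAs brought the median from -0.53 to -0.33, at percentile 0.225 of random lists. That fit included GC-rich entries with large ratios, such as miR-663a (8.34). By contrast, the 177 miRNAs off the cluster and the list of other RNA classes, with GC between the cluster's quartiles, had a median of -0.034. Among random lists matched on GC, the cluster's median of -0.53 lay at percentile 0. The matched lists speak only against GC as the whole cause, so whether GC accounts for part stays open. These tests used precursor GC, and the GC of the sequenced parts was not measured. The random lists also drew miRNAs singly, unlike neighbours in a cluster. With 1 library per group, an effect of HGF on this cluster is a hypothesis that cannot be separated from a difference between 2 cultures or libraries.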
